A study of Canis lupus familiaris with 34 samples.

How the data were processed

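Gene expression was measured by RNA sequencing (total RNA, TruSeq RNA v2 libraries, HiSeq 2000, per the labels) in 34 dog samples. The labels give 30 libraries of primary osteosarcoma, 1 of a metastasis, 2 of osteosarcoma cell lines and 1 of an osteoblast culture. The deposited table holds 1 row per gene and 1 column per library, with 23988 rows. Its header names no unit. The values were read as FPKM (fragments per kilobase of transcript, scaled to the size of the library) deposited by the authors, because the submitters' processing notes list Cufflinks 2.2.1 beside TopHat2 2.0.13, FastQC 0.11.2 and the dog assembly canFam3, and because the column sums differ from each other. The notes give no order of steps, no gene annotation and no parameters, so these are not given in the sources used here. The upper quartiles of the columns lie between 12.1 and 14.5, which leaves a scaling between libraries by the authors possible. The table carries the word masked in its name, and what was masked is not given in the sources used here.

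Read counts are not available, so the sequencing depth of each library is unknown and no counting interval was computed. A relative figure was taken from low values. Among values under 0.3 FPKM the ratios to library DOS.46 gather at a fixed value per library times ratios of whole numbers (up to 6, within 0.02 on the log2 scale). Between 48.2% and 63.5% of the ratios fell there, against 17.8% for evenly spread ratios. The fixed value was chosen to bring ratios near such positions, and the 17.8% makes no allowance for that choice. The fixed value, read as the FPKM of 1 fragment relative to that in the median library, ranged from 0.758 to 2.04.

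Of the rows, 9653 carry only an Ensembl identifier and were not given a name, since the reference table at hand (13096 of the 14335 other names found in it) belongs to another genome build and holds no such identifiers. Genes on those rows take part in the counts over all genes and in no gene list. Genome coordinates are not printed for the same reason. Rows with at least 1 FPKM in at least 2 libraries were kept (15165, of which 11824 have a gene symbol), and 1 FPKM was added before log2 transformation. Libraries DOS.46 and DOS.46.2 share a title number, and their deviations from the mean of the primary tumours correlated at r = 0.744 across genes, so they were averaged on the log2 scale and counted as 1 tumour. This leaves 29 primary tumours.

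The 2 lines were compared with the 29 primary tumours gene by gene in limma 3.58.1 under R 4.3.3 (lmFit and eBayes with trend and robust options, two-sided), with Benjamini-Hochberg adjustment over the 15165 genes and a threshold of 0.05. Gene lists for cell types, pathways and osteosarcoma genes were fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and most of the alternative settings. Lists with at least 5 members past the filter (20 lists) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation, fry, and an exact two-sided permutation test of list scores over the 465 ways to draw 2 of 31 samples (smallest possible p 0.00215). A list score is the mean log2(FPKM + 1) of its members. The lists cover the cell cycle, T cells, B and plasma cells, macrophages, interferon response, immune checkpoints, neutrophils, bone matrix, osteoclasts, cartilage, fibroblasts, endothelium, smooth muscle and pericytes, skeletal muscle, erythroid cells, epithelium, hypoxia and glycolysis, p53 targets, immediate early genes and osteosarcoma genes. The lists for MHC class II, mast cells, adipocytes and lung epithelium kept fewer than 5 members and were not tested.

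Among the primary tumours, the coherence of a list is the mean Pearson correlation between its members, ranked among 10000 random lists of the same size matched on expression in 20 bins. Lists were also tested for members among the 10% of genes with the largest standard deviation of log2(FPKM + 1) (Fisher's exact test, two-sided, background all genes past the filter). For 17 pairs of lists fixed in advance, scores made of gene z-scores were correlated across tumours with 100000 permutations, adjusted over the pairs, and again without the 2 tumours farthest from the median of the first score. An 18th pair was not run, since the MHC class II list kept 2 members. The metastasis and the osteoblast culture have no replicate and were described by differences, ranges and ranks without a test. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used beside R.

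Named genes followed a rule fixed in advance. For the lines these are the 10 genes with the largest rise and the 10 with the largest fall among genes with a symbol, an adjusted p below the threshold and both lines beyond every primary tumour, and for each list the 3 members with the largest called change, or the 2 with the smallest adjusted p where none passed. For variation these are the 15 genes with the largest standard deviation and the 3 most variable members of each list discussed. For the metastasis these are the 10 highest and 10 lowest genes against the tumour mean among those outside the range of all primary tumours and of the same sign against DOS.6. For the osteoblast culture these are the 10 genes on each side by the smaller of the differences from the lines. Any gene of the osteosarcoma list could be named.

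Alternatives were a pseudocount of 0.1 FPKM, no filter, scaling to the upper quartile, quantile normalisation, DOS.46 and DOS.46.2 as 2 tumours, each line left out, the title number as a fixed or a random block, the osteoblast culture added to the lines, eBayes without trend and robust options, the 5% most variable genes, and scores without the first principal component. Added after the data were seen were DOS.100 and DOS.32 as 1 tumour and rows with a symbol only. The limma comparison was tested on simulated data with 100 changed genes at each of the log2 sizes 2 and 4 among 15165. It recovered 70% and 97% of them with 8 false calls among 175. The simulated genes were drawn independently of each other, and the simulated lines had the spread of the tumours. These figures therefore do not give the error rate for correlated genes or for lines that resemble each other. In simulated tumours the coherence ranking placed 2 of 2 lists with a shared factor, and 0 of 18 without one, at or over the 95th percentile. Breeds were not compared, because every sample is labelled Golden Retriever while the series description also names Rottweilers. One gene among the 10 largest rises in the lines is not reported here.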

Results

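Gene expression was profiled in osteosarcoma of the dog, a malignant tumour of bone-forming cells. The 34 RNA sequencing libraries comprise 30 of primary tumours, 1 of a metastasis, 2 of osteosarcoma cell lines (OSCA.8 and OSCA.78) and 1 of a culture of osteoblasts, the cells that lay down bone matrix. A pair of primary tumour libraries, DOS.46 and DOS.46.2, entered as 1 tumour, which leaves 29. Values, whose unit the table does not state, were read as FPKM and compared after adding 1 FPKM and taking log2. Summed FPKM per library ranged from 479053 to 1418310 with a median of 623084, and between 15328 and 17711 of the 23988 genes had a value above 0. The highest sum belonged to the osteoblast culture. The 10 most abundant genes took between 7.14% and 39.1% of a library's sum. Depth in reads is unknown. The limma p-values of single genes below rest on the spread between these samples, which may in part be technical. With 2 lines against 29 tumours, that spread comes almost wholly from the tumours. Camera sets the genes of a list against other genes, at its preset with an assumed correlation of 0.01. Fisher's exact test takes genes as units, which are not independent, and measures no spread between samples. Genes of wide interest such as MYC and RUNX2 could not be looked up by symbol. Whether they are among the 9653 genes that carry no symbol is unknown.

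The first comparison asked how the cell lines, described by the submitters as derived from earlier primary tumours, differ from tumour tissue. Over all genes tested, 15 of 17 macrophage genes, 10 of 12 endothelial genes and 5 of 11 bone matrix genes fell in the lines. The 3 lists fell by camera at its preset correlation and missed the threshold with an estimated correlation (adjusted p = 0.0567, 0.208 and 0.208). Bone sialoprotein IBSP, a protein of mineralised bone, averaged 1452 ± 1493 FPKM (SD, n = 29) in primary tumours and stood at 1.96 FPKM in OSCA.8 and 0.717 in OSCA.78. The complement component C1QC, made by macrophages, averaged 94.4 ± 77.7 FPKM (SD, n = 29) in tumours against 0.133 and 0.142 in the lines. Genes of the interferon response and of the cell cycle rose as groups by the same test. Both calls ended with an estimated correlation (adjusted p = 0.710 each) and without OSCA.78 (camera adjusted p = 0.288 and 0.114), and neither list passed the exact permutation test (adjusted p = 0.0676 and 0.238). Over all genes, 2489 of 15165 differed (limma, adjusted p below the threshold), 1288 higher and 1201 lower in the lines.

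The macrophage list fell as a group (camera adjusted p = 5.4e-17, mean log2 fold change -4.08), a call that missed the threshold at an adjusted p = 0.0567 with an estimated correlation. Of its 17 measured members, 15 fell over all genes tested and 17 when adjusted over the list alone, and none rose. TYROBP, a signalling adaptor of myeloid cells, changed by -6.29 ± 0.86 (SE, limma adjusted p = 4.7e-06), C1QC by -6.01 ± 0.72 (limma adjusted p = 4.6e-07) and the lysosomal protein LAPTM5 by -5.99 ± 0.81 (limma adjusted p = 4.2e-06). The antigen presentation gene CD74 fell by 7.30 on the log2 scale (SE 0.77, limma adjusted p = 3.3e-08), from 277 FPKM in tumours to 0.234 and 0.497 in the lines. CIITA, the activator of MHC class II genes, changed by -1.37 (limma adjusted p = 0.0405, and at -1.37 each 0.364 without OSCA.78 and 0.166 without OSCA.8). These 2 genes were the members of the MHC class II list that passed the filter.

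The endothelial list fell as well (camera adjusted p = 2.9e-10, mean log2 fold change -3.59, adjusted p = 0.208 with an estimated correlation). Of 12 members, 10 fell over all genes and 11 when adjusted over the list alone. The diaphragm protein of vessel walls PLVAP changed by -7.25 ± 0.81 (SE, limma adjusted p = 1.3e-07), the adhesion molecule PECAM1 by -5.95 ± 0.91 (limma adjusted p = 2.6e-05) and the cadherin CDH5 by -4.81 ± 0.85 (limma adjusted p = 1.7e-04). PLVAP averaged 260 ± 306 FPKM (SD, n = 29) in tumours and 0.145 and 0.165 in the lines. Among smooth muscle and pericyte genes, 3 of 8 fell over all genes and 3 when adjusted over the list alone, led by the pericyte marker RGS5 at -4.91 ± 0.79 (SE, limma adjusted p = 5.1e-05), with KCNMB1 at -3.02 and MCAM at -2.43. The list itself did not pass (camera adjusted p = 0.0731), and without OSCA.78 it did (0.00544) while the calls of KCNMB1 and MCAM ended (limma adjusted p = 0.219 and 0.0761) at larger changes of -3.21 and -3.44. Both calls also ended without OSCA.8 (0.127 and 0.385, at -2.83 and -1.43).

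Bone matrix genes fell (camera adjusted p = 1.4e-05, mean log2 fold change -3.44, adjusted p = 0.208 with an estimated correlation). Of 11 members, 5 fell over all genes and 8 when adjusted over the list alone. IBSP changed by -8.32 ± 1.35 (SE, limma adjusted p = 7.1e-05), osteopontin SPP1 by -5.57 ± 1.23 (limma adjusted p = 0.0022) and osteomodulin OMD by -5.14 ± 1.10 (limma adjusted p = 0.0016). Without OSCA.78 the call of IBSP held (0.0175) and those of SPP1 (0.179, at -4.70) and OMD (0.255, at -3.68) ended. Fibroblast genes gave 2 falls among 11 over all genes and 4 when adjusted over the list alone, the matrix protein POSTN (-5.50 ± 1.59 SE, limma adjusted p = 0.0166) and the protease FAP (-3.14 ± 0.60 SE, limma adjusted p = 4.4e-04). The list missed the threshold (camera adjusted p = 0.0576), and without OSCA.78 neither gene passed (0.476 and 0.322, at -3.93 and -1.68).

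Interferon response genes rose (camera adjusted p = 4.3e-04, mean log2 fold change 1.41, adjusted p = 0.710 with an estimated correlation). Of 16 members, 8 rose over all genes and 9 when adjusted over the list alone. The ubiquitin-like ISG15 changed by 5.29 ± 1.09 (SE, limma adjusted p = 0.0011), the mitochondrial kinase CMPK2 by 2.83 ± 0.60 (limma adjusted p = 0.0012) and the sensor of double-stranded RNA OAS1 by 2.74 ± 0.62 (limma adjusted p = 0.0025). ISG15 stood at 1492 FPKM in OSCA.78 and 343 in OSCA.8, against 32.7 ± 41.5 (SD, n = 29) in tumours. Without OSCA.78 the call of the list ended (camera adjusted p = 0.288), as did those of ISG15, CMPK2 and OAS1 (limma adjusted p = 0.163, 0.412 and 0.571), which in OSCA.8 alone differed from tumours by 4.23, 1.501 and 1.20 on the log2 scale. The list score was 5.12 in OSCA.78, above every primary tumour (highest 4.56), and 3.29 in OSCA.8.

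Cell cycle genes rose by less (camera adjusted p = 0.0229, mean log2 fold change 0.77, adjusted p = 0.710 with an estimated correlation), with 4 of 20 members over all genes and 6 when adjusted over the list alone. The proliferation marker MKI67 changed by 2.03 ± 0.70 (SE, limma adjusted p = 0.0436), the replication helicase subunit MCM5 by 1.85 ± 0.61 (limma adjusted p = 0.0346) and the mitotic kinase PLK1 by 1.72 ± 0.60 (limma adjusted p = 0.0460). Without OSCA.78 the list (camera adjusted p = 0.114) and these genes (limma adjusted p = 0.717, 0.710 and 0.716, at 1.04, 0.918 and 0.901) no longer passed, and after quantile normalisation the list's adjusted p was 0.0632. T cell genes fell as a list (camera adjusted p = 0.00856, mean log2 fold change -0.99, adjusted p = 0.710 with an estimated correlation) while 0 of 15 members passed by limma over all genes or when adjusted over the list alone. Nearest were CD2 at -1.84 (limma adjusted p = 0.0557) and ZAP70 at -1.22 (0.116), and without OSCA.8 the list's camera adjusted p was 0.0545.

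The other lists were not called, and some held single genes that passed. Of the osteosarcoma genes (camera adjusted p = 0.426, 3 of 11 members over all genes and 3 when adjusted over the list alone), the cyclin-dependent kinase CDK4 rose by 1.78 ± 0.33 (SE, limma adjusted p = 3.4e-04), at 320 and 323 FPKM in the lines against 97.5 ± 31.8 (SD, n = 29) in tumours. The chromatin remodeller ATRX changed by -1.22 (limma adjusted p = 0.0020) and CDC5L by -1.38 (limma adjusted p = 0.0241), and both calls ended without OSCA.78 (0.327 and 0.352, at -0.793 and -1.26), that of CDC5L also without OSCA.8 (0.0930, at -1.49). RB1 stood at -1.04 (limma adjusted p = 0.104). Among epithelial genes (camera adjusted p = 0.441), EPCAM rose by 3.39 ± 0.46 (SE, limma adjusted p = 4.2e-06, and by 2.13 with 0.0367 without OSCA.78) and ESRP1 by 2.25 ± 0.67 (limma adjusted p = 0.0195, and 0.595 at 1.34 without OSCA.78), which are 2 of 6 members over all genes and 2 when adjusted over the list alone. The mean of that list was 0.64 and its median -0.02. Among checkpoint genes (camera adjusted p = 0.474), PDCD1 rose by 2.10 (limma adjusted p = 0.0049) and LAG3 fell by 1.88 (limma adjusted p = 0.0076), neither called without OSCA.78 (0.294 and 0.144, at 1.67 and -1.98), and LAG3 not without OSCA.8 (0.0804, at -1.79). These are 2 of 7 members over all genes, and 3 passed when adjusted over the list alone.

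Cartilage genes went both ways (camera adjusted p = 0.605), with MATN3 up by 1.34 (limma adjusted p = 0.0358) and aggrecan ACAN down at -3.70 (limma adjusted p = 0.0305) over all genes, and 4 of 8 members passing when adjusted over the list alone. Without OSCA.78 the limma adjusted p was 0.740 for MATN3 (at 0.608) and 0.324 for ACAN (at -3.69), and without OSCA.8 it was 0.138 for ACAN (at -3.71). Of the p53 targets (camera adjusted p = 0.809), SESN2 rose by 1.67 (limma adjusted p = 0.0025, and 0.0899 at 1.71 without OSCA.78) as 1 of 10 members over all genes and 1 when adjusted over the list alone. Osteoclast genes (camera adjusted p = 0.0576, and 0.0117 without OSCA.78), B and plasma cell genes (0.0769), immediate early genes (0.0917), skeletal muscle genes (0.292), neutrophil genes (0.661) and erythroid genes (0.905) held 0 called members by limma over all genes and 0 when adjusted over the list alone. Hypoxia genes (camera adjusted p = 0.791) held 0 over all genes and 2 when adjusted over the list alone. Among the lists too short to test, 2 lung epithelium genes passed, ABCA3 at 1.93 (limma adjusted p = 0.0026) and HOPX at -2.45 (limma adjusted p = 0.0327), and without OSCA.78 neither did (0.287 and 0.296, at 1.42 and -2.60), nor HOPX without OSCA.8 (0.173, at -2.31). The 4 mast cell genes and the 4 adipocyte genes held 0 that passed.

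Among genes with a symbol that lay beyond every tumour in both lines, the largest rise was that of PLA2G3, a secreted phospholipase, at 5.46 ± 0.39 (SE, limma adjusted p = 6.1e-12), with 41.6 FPKM in OSCA.8 and 69.9 in OSCA.78 against 0.364 ± 0.746 (SD, n = 29) in tumours. The cadherin CDH6 rose by 4.65 ± 0.37 (SE, limma adjusted p = 6.5e-11), from 0.509 to 38.1 and 30.9 FPKM. Fibrillin FBN2 (4.78), the neuronal growth protein GAP43 (4.66), MGST1 (4.60), NPTX1 (4.31), the homeobox gene TLX2 (4.26) and SHISA2 (4.03) were, with ISG15, also among the 10 largest rises. The largest falls besides IBSP, CD74, PLVAP, TYROBP and C1QC were C1QTNF5 (-7.05), the WNT inhibitor WIF1 (-6.44), FXYD1 (-6.41), NDUFA4L2 (-6.40) and the protease PRSS23 (-6.00). C1QTNF5 averaged 186 ± 85.02 FPKM (SD, n = 29) in tumours and stood at 0.269 and 0.286 in the lines (limma adjusted p = 4.1e-13). In both lines at once, 613 genes lay above and 1107 below all 29 tumours, which is 4.04% and 7.30% of the genes against 0.215% on each side by chance.

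With OSCA.8 as the only line 344 genes were called (199 higher and 145 lower), 320 of them among the 2489, and the calls of FBN2, GAP43, WIF1 and PRSS23 ended (limma adjusted p = 0.163, 0.0964, 0.313 and 0.0520) at log2 fold changes of 3.70, 4.27, -5.18 and -6.01. With a single line left, a call can end while the change stays as large, as for GAP43 and PRSS23. With a pseudocount of 0.1 FPKM or scaling to the upper quartile the balance turned, to 1121 higher and 1639 lower and to 1118 higher and 1291 lower. An exact permutation test of list scores, lines against tumours, passed for macrophage, endothelial and bone matrix genes (adjusted p = 0.0143 each), fibroblast genes (0.0323) and B and plasma cell genes (0.0430), and fry (limma) passed for the same 5 lists (adjusted p = 1.1e-06, 2.2e-04, 4.1e-04, 0.0291 and 0.0291).

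**Figure D1:**
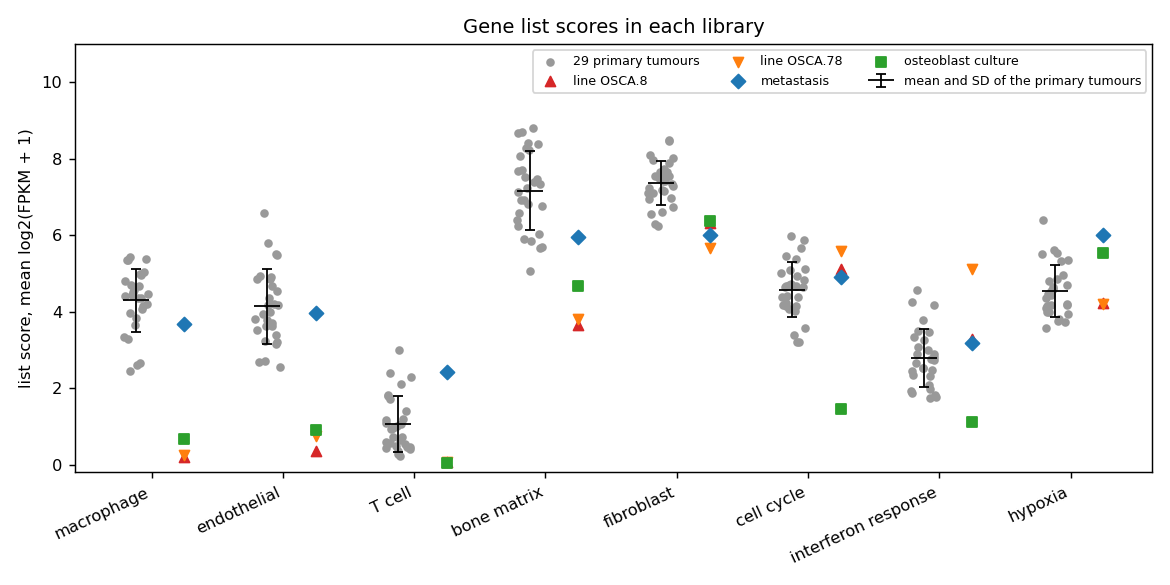
Score of 8 gene lists in each library, as the mean log2(FPKM + 1) of the list's members, with the primary tumours as grey points (mean and SD in black), the 2 lines as triangles, the metastasis as a diamond and the osteoblast culture as a square. The lines and the osteoblast culture lie below all 29 primary tumours for macrophage, endothelial, bone matrix and T cell genes. The osteoblast culture also lies below them for cell cycle and interferon response genes.

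**Figure D2:**
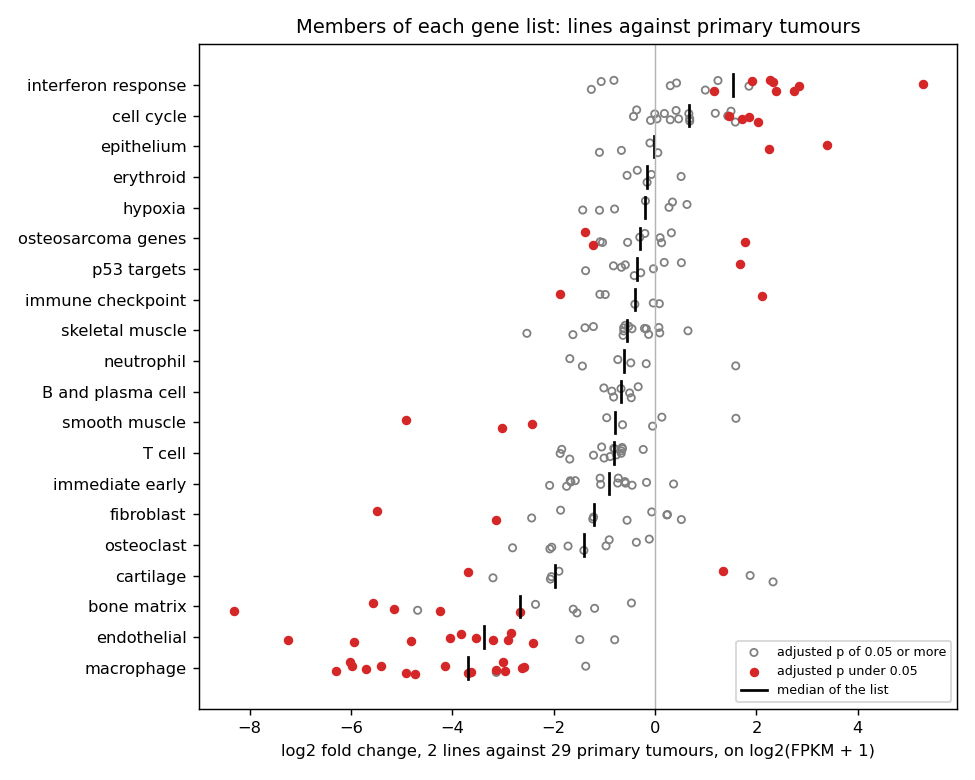
Log2 fold change of each member of 20 gene lists between the 2 lines and 29 primary tumours, filled where the adjusted p from limma passed the threshold, with the median of each list as a black bar. Of the macrophage genes 15 of 17 passed and fell, and of the interferon response genes 8 of 16 passed and rose.

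The second set of comparisons described how the primary tumours differ among themselves. Lists with most of their members among the 10% most variable genes included those for cartilage, bone matrix, macrophages, endothelium and the immediate early response, genes that cells switch on within minutes of a stimulus. With a pseudocount of 0.1 FPKM the cartilage and bone matrix lists still passed (Fisher's exact test, adjusted p = 1.4e-05 and 0.0020) and the other 3 did not (0.806, 0.524 and 0.316 in the order given). DMP1, a matrix protein of mature bone cells, ranged from 0.306 to 762 FPKM across 29 tumours (SD 2.80 on the log2 scale), and SOST, the osteocyte inhibitor of WNT signalling, from 0.0373 to 429. By SD DMP1 ranked 70 among all genes, as the first with a symbol. The 15 most variable genes with a symbol also included MMP1 (0.0702 to 172 FPKM), WIF1 (13.7 to 8116), the cartilage link protein HAPLN1 (0.248 to 605), COL11A1 (0.290 to 633), POSTN (7.82 to 4432), SFRP4 (1.22 to 699), THBS4 (0.633 to 316), TNN (1.89 to 1662) and SCRG1 (0 to 536). The remaining ones were PAGE3, a member of a testis antigen family (0 to 287 FPKM), the neuropeptide NPY (0.0876 to 505), BCHE (0.0518 to 147) and C11ORF85 (1.10 to 2203).

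The 10% most variable genes (1516 genes with an SD of at least 0.999, against a median SD of 0.54) held more members than the background predicts for 9 of 20 lists. They held 12 of 14 immediate early genes (Fisher's exact test, adjusted p = 1.4e-09), with FOS from 9.23 to 1412 FPKM and EGR1 from 7.26 to 487. They held 7 of 8 cartilage genes (adjusted p = 3.6e-06 by the same exact test), with COMP from 1.79 to 257 FPKM, and 8 of 11 bone matrix genes (4.9e-06), with IBSP from 48.6 to 5170. Macrophage genes (13 of 17, 1.5e-09), endothelial genes (9 of 12, 1.1e-06), fibroblast genes (7 of 11, 7.5e-05), skeletal muscle genes (8 of 16, 1.7e-04), smooth muscle and pericyte genes (5 of 8, 0.0011) and osteoclast genes (4 of 9, 0.0184) followed by Fisher's exact test. No cell cycle gene (0 of 20, 0.363) was among them at this cut, just above the SD of TOP2A (0.996, from 5.64 to 154 FPKM). Cell cycle members there were 3 of 20 after quantile normalisation, 5 of 21 without the filter and 5 of 20 with symbols only (exact test adjusted p = 0.592, 0.0955 and 0.0716). The other lists that did not pass were interferon response (4 of 16, 0.136), T cell (3 of 15, 0.283), neutrophil (2 of 6, 0.190), erythroid (2 of 5, 0.148), checkpoint (1 of 7, 0.652), hypoxia (1 of 7, 0.652), osteosarcoma (0 of 11, 0.685), p53 target (0 of 10, 0.685), epithelial (0 of 6, 1) and B and plasma cell genes (0 of 7, 1) in the same exact test. With a pseudocount of 0.1 FPKM, which gives weight to genes near 0, the macrophage (0.806), endothelial (0.524), smooth muscle (0.340), immediate early (0.316) and fibroblast lists (1) no longer passed, and the T cell (6 of 15, 0.00744) and neutrophil lists (4 of 6, 0.00506) did. Among the 5% most variable genes the macrophage (0.125), endothelial (0.236) and smooth muscle lists (0.127) did not pass. The interferon response list passed without the filter (8 of 16, 1.9e-04) and with symbols only (5 of 16, 0.0338), as did hypoxia genes with symbols only (3 of 7, 0.0466).

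Genes of a list varied together. The mean correlation between members across the 29 tumours was 0.764 for endothelial genes, 0.733 for cell cycle genes, 0.733 for T cell genes, 0.704 for immediate early genes, 0.687 for interferon response genes and 0.644 for osteoclast genes. In 19 of 20 lists it reached the 95th percentile of random lists matched on expression. The exception was the fibroblast list (mean correlation 0.172, percentile 94.9), which lay past that percentile without the filter (96.1), after quantile normalisation (99.4), with DOS.100 and DOS.32 as 1 tumour (95.4) and with symbols only (98.3). The osteosarcoma genes gave the lowest mean correlation, 0.0710 (percentile 96.5). In single tumours, endothelial genes peaked in DOS.81, with PECAM1 at 490 FPKM against a median of 66.5, and osteoclast genes were high in DOS.28, with ATP6V0D2, a proton pump subunit of bone-resorbing cells, at 55.5 against a median of 6.91. Hypoxia genes peaked in DOS.84, where EGLN3 reached 171 FPKM against a median of 7.93.

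Across 29 tumours the macrophage score rose with the osteoclast score, 2 cell types of the same lineage (Pearson r = 0.564, permutation p = 0.00147, adjusted p = 0.0145 over 17 pairs). Spearman's rho was 0.567 (permutation p = 0.00162, adjusted p = 0.0275), and r was 0.491 without the 2 tumours farthest from the median macrophage score (permutation p = 0.00935). It was 0.651 and 0.530 in the 14 tumours with the lower and the 15 with the higher summed FPKM (permutation p = 0.0117 and 0.0420). DOS.100 and DOS.32, which resembled repeats of 1 sample (below), counted as 2 tumours in this correlation. Both were low for macrophage (-1.52 and -1.34) and osteoclast genes (-1.01 and -0.980). The 2 tumours farthest from the median macrophage score were DOS.100 and DOS.116, so DOS.32 stayed in when these were left out. DOS.100 lies in the lower set and DOS.32 in the higher, so the 2 sets are not independent. The cell cycle score fell as the score of p53 targets rose (r = -0.556, permutation p = 0.00171, adjusted p = 0.0145). Its rho was -0.493 (permutation p = 0.00737, adjusted p = 0.0555) and r was -0.468 without the 2 farthest tumours (permutation p = 0.0140). In the 14 tumours with the lower summed FPKM r was -0.230 (permutation p = 0.426) and in the other 15 it was -0.565 (permutation p = 0.0286), a difference that was not tested. The cell cycle score itself fell with summed FPKM (rho = -0.650, permutation p = 2.1e-04, adjusted p = 0.0042), the only one of 20 lists to do so past the threshold. Erythroid scores of DOS.85, DOS.111 and DOS.114 (2.48, 2.35 and 2.25) stood apart from the rest (at most 0.960). The planned correlation of erythroid with neutrophil scores passed over 29 tumours by Pearson (adjusted p = 0.0208) and not by Spearman (0.331). Of those 3, DOS.85 and DOS.114 also had the highest neutrophil scores (mean z-score 2.46 and 2.31), and DOS.111 did not (0.0323). In the other 26 tumours alone r was 0.0176 and rho 0.0578 (permutation p = 0.932 and 0.777). The 14 remaining pairs did not pass the adjusted threshold, the nearest being cell cycle with endothelial genes (r = -0.449, rho = -0.394, permutation p = 0.0151 and 0.0360, adjusted p = 0.0641 and 0.128) and T cell with B and plasma cell genes (r = 0.431, rho = 0.478, permutation p = 0.0201 and 0.00980, adjusted p = 0.0683 and 0.0555).

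**Figure D3:**
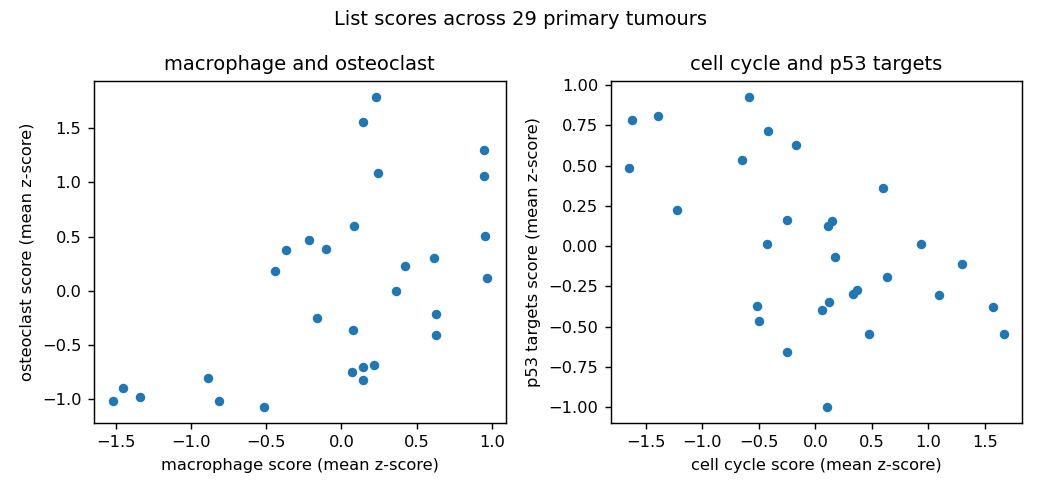
List scores (mean gene z-score of log2(FPKM + 1), no unit) of 29 primary tumours, 1 point per tumour, for macrophage against osteoclast genes on the left (r = 0.564) and cell cycle genes against p53 targets on the right (r = -0.556). The left pair rises together and the right pair runs in opposite directions.

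The third comparison set the only metastasis, DOS.6M, against the primary tumours, 1 of which (DOS.6) carries the same title number. With no replicate there was no test. The metastasis held the highest levels of the stress-induced transcription factor ATF3, at 361 FPKM against 86.8 in DOS.6 and 12.99 ± 16.6 (SD, n = 29) in primary tumours, and of the tryptophan-degrading enzyme IDO1, at 31.4 against 10.1 and 2.55 ± 4.67. It held the lowest level of the chemokine CXCL14, at 2.45 FPKM, close to the 2.96 of the lowest primary tumour. CXCL14 stood at 76.4 FPKM in DOS.6 and at 348 ± 651 in primary tumours. The transcription factor PRRX1 was also lowest in the metastasis, at 12.2 FPKM against 161 ± 81.6. Across genes, its deviations from the mean of primary tumours correlated most with those of DOS.6 (r = 0.510, next DOS.116 at 0.195), where genes are not independent replicates.

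The 10 highest differences from the tumour mean, in log2, were those of ATF3 (5.21), GPAT2 (5.12), the cartilage collagen COL9A1 (4.52), the insulin receptor substrate IRS4 (4.47), the homeobox gene BARX2 (4.25), NRN1 (4.07), the homeobox gene OTX2 (3.97), LIN7A (3.94), IDO1 (3.83) and TCF24 (3.67). For ATF3, GPAT2, IRS4 and OTX2 the highest primary tumour was DOS.6 itself, at 86.8, 39.3, 10.9 and 3.93 FPKM. The 10 lowest were those of CXCL14 (-5.35), LRRC15 (-3.78), B3GNT9 (-3.46), MORF4L2 (-3.43), PRRX1 (-3.43), VIT (-3.36), EDIL3 (-3.28), MXRA5 (-3.23), MXRA8 (-3.21) and IGFBP6 (-3.16). B3GNT9 was near 0 both in the metastasis (1.62e-06 FPKM) and in the lowest primary tumour (0.000131), so its place below the range carries little weight. The order depends on the pseudocount. With 0.1 FPKM the highest of the genes named were IRS4 (7.35), OTX2 (6.83) and GPAT2 (6.17), with ATF3 at 5.39, and the lowest were B3GNT9 (-6.52) and VIT (-5.88), with CXCL14 at -5.76.

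By list score the metastasis ranked first of 30, with the 29 primary tumours, for epithelial genes and for checkpoint genes, and it ranked 2 for T cell, immediate early and hypoxia genes, 3 for cartilage genes and 30 for fibroblast genes. Among the 29 primary tumours DOS.6 ranked 3 for T cell, immediate early and hypoxia genes, 4 for checkpoint, 9 for epithelial, 12 for cartilage and 23 for fibroblast genes. Several members lay outside the range of every primary tumour and were chosen for naming after their values were seen. Above it were PDCD1, an inhibitory receptor of T cells, at 5.34 FPKM and EPCAM at 6.49. The highest primary tumour for PDCD1 was DOS.6 at 4.53 FPKM, and EPCAM reached at most 2.76 in primary tumours. Also above the range were the glycolytic enzymes HK2 (85.8, against 12.1 ± 9.80 SD, n = 29) and ENO1 (613), and the immediate early gene JUN (743). Below it were the collagen genes COL1A2 (1930 FPKM against 9286 ± 5955 SD, n = 29) and COL5A1 (89.1), and the matrix protein SPARC (1386). Of the osteosarcoma genes, CDC5L lay above (118 FPKM, with DOS.6 next at 69.4), EZR below (76.6 against 187 ± 69.4 SD, n = 29) and DLG2 below (0.0265). Ranks for other lists were 4 for osteosarcoma genes, 8 for neutrophil, skeletal muscle and erythroid genes, 9 for interferon response, 10 for cell cycle and p53 target genes, 14 for smooth muscle, 16 for endothelial, 17 for B and plasma cell, 24 for macrophage and osteoclast and 25 for bone matrix genes. With a pseudocount of 0.1 FPKM the osteosarcoma genes ranked 11, p53 targets 7 and T cell genes 3, and after quantile normalisation erythroid genes ranked 15 and immediate early genes 3.

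In all, 759 genes lay above and 536 below the range of the 29 primary tumours, 5.005% and 3.53% of 15165 against 3.33% on each side by chance. Single primary tumours set against the other 28 had between 174 and 1329 genes above (median 458) and between 109 and 1036 below (median 404), so the metastasis lay within the spread of the tumours. After quantile normalisation the balance turned, with 682 above and 802 below.

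The fourth comparison set the osteoblast culture, the only library not from a tumour, against the 2 osteosarcoma lines, again with no replicate and no test. Cell cycle genes were lower in the osteoblast culture throughout, 20 of 20 by more than 1 on the log2 scale against each line. MKI67 stood at 0.339 FPKM in the culture against 21.2 in OSCA.8 and 86.8 in OSCA.78, and the nucleotide reductase RRM2 at 0.594 against 73.6 and 103. Interferon response genes were lower as well, with ISG15 at 1.27 FPKM against 343 and 1492. Of the smooth muscle and pericyte genes 6 of 8 were higher by more than 1 against each line, with TAGLN at 47085 FPKM against 321 and 1647. The pericyte marker RGS5 was near 0 in the culture and both lines (0.0663 against 0.0325 and 0.0345). List members in this comparison that are not among the 10 highest or lowest genes were chosen after their values were seen.

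The median difference of the cell cycle list was -4.06, below all 10000 random lists matched on expression, and that of the interferon response list was -3.17, also below all of them, with 12 of 16 members lower against each line. Against OSCA.8 alone the interferon response median was -1.69 and against OSCA.78 alone -4.63, both again below all random lists. The smooth muscle and pericyte list had a median of 3.50, above all random lists, with 6 of 8 members higher, among them KCNMB1 (211 FPKM against 0.0289 and 0.338). Immediate early genes had a median of 2.75, also above all random lists, with 11 of 14 higher, such as BTG2 (99.6 FPKM against 4.06 and 4.92). The p53 targets had a median of 1.30 (percentile 99.7, but 0.58 and 80.2 against OSCA.8 alone and 1.85 and 99.99 against OSCA.78 alone), with 4 of 10 higher, among them the death receptor FAS (199 FPKM against 0.0251 and 18.1), AEN (156 against 5.82 and 7.02) and SESN2 (109 against 10.1 and 9.49), while SESN1 was lower (1.43 against 19.7 and 11.9). Hypoxia genes had a median of 1.30 (percentile 96.3, and 84.5 against OSCA.8 alone). Bone matrix genes had a median of 1.15 (percentile 99.4), with 3 of 11 higher and 0 lower by more than 1 against each line. SP7, a transcription factor of osteoblasts, stood at 24.7 FPKM against 0.201 and 5.08, while SPP1 stood at 4.38 against 19.0 and 5.01. Cartilage genes had a median of -1.21 (percentile 0.130). The bone matrix median was 0.25 (percentile 79.3) after quantile normalisation, 0.45 (percentile 79.3) without OSCA.8 and 0.86 (percentile 97.6) without OSCA.78.

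Other lists stood nearer to 0. The median difference was 0.51 for fibroblast genes (percentile 38.2, with -0.19 after quantile normalisation, -0.08 at percentile 4.90 against OSCA.8 alone and 1.3998 at percentile 94.9 against OSCA.78 alone), 0.17 for endothelial (99.6), 0.13 for skeletal muscle (95.6), 0.11 for osteoclast (92.7), 0.10 for macrophage (99.6), -0.08 for epithelial (43.2), -0.09 for erythroid (34.2), -0.01 for neutrophil (47.0) and -0.18 for osteosarcoma genes (18.2), and 0 for T cell, B and plasma cell and checkpoint genes. With a pseudocount of 0.1 FPKM and after quantile normalisation in turn, the median was 0.62 and 0.48 for endothelial, 0.57 and 0.46 for skeletal muscle, 0.83 and 0.57 for osteoclast (percentiles 98.7 and 98.3), 0.55 and 0.43 for macrophage and -0.54 and -0.36 for osteosarcoma genes. Medians of epithelial (0.17), erythroid (0.20) and neutrophil genes (0.02) were above 0 after quantile normalisation. RB1 was higher in the culture (9.92 FPKM against 4.06 and 4.04) and CCNE1 lower (2.07 against 7.74 and 8.76), and CDK4 stood at 205 against 320 and 323.

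The 10 genes highest in the culture were NDUFA4L2 (4064 FPKM against 2.78 in OSCA.8 and 0.307 in OSCA.78), FXYD1 (768 against 0.383 and 0.304), PRSS23, EFEMP2, WFDC1, the actin gene ACTA1 (708 against 0.795 and 2.08), S100A16, PAPSS2, the proteoglycan PRELP and FAM26E, the last by 7.45 on the log2 scale against the nearer line. NDUFA4L2, FXYD1 and PRSS23 were also among the 10 largest falls in the lines against primary tumours. The 10 lowest were ISG15, FABP3, the glypican GPC3 (0.0202 FPKM against 99.4 and 74.7), FBN2, TGFBI, SHISA2, MGST1, VCAM1, RRM2 and PLA2G3 (0.0406 against 41.6 and 69.9). The order among these genes changed with a pseudocount of 0.1 FPKM, as for PAPSS2 (7.58 to 10.7 against the nearer line) and GPC3 (-6.21 to -9.28). In all, 2412 genes were higher and 1441 lower by more than 1 on the log2 scale against each line. Quantile normalisation brought the counts to 1387 and 1323. Against OSCA.78 alone they were 3234 and 2308, against OSCA.8 alone 3651 and 2595, and with a pseudocount of 0.1 FPKM 2771 and 2268.

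**Figure D4:**
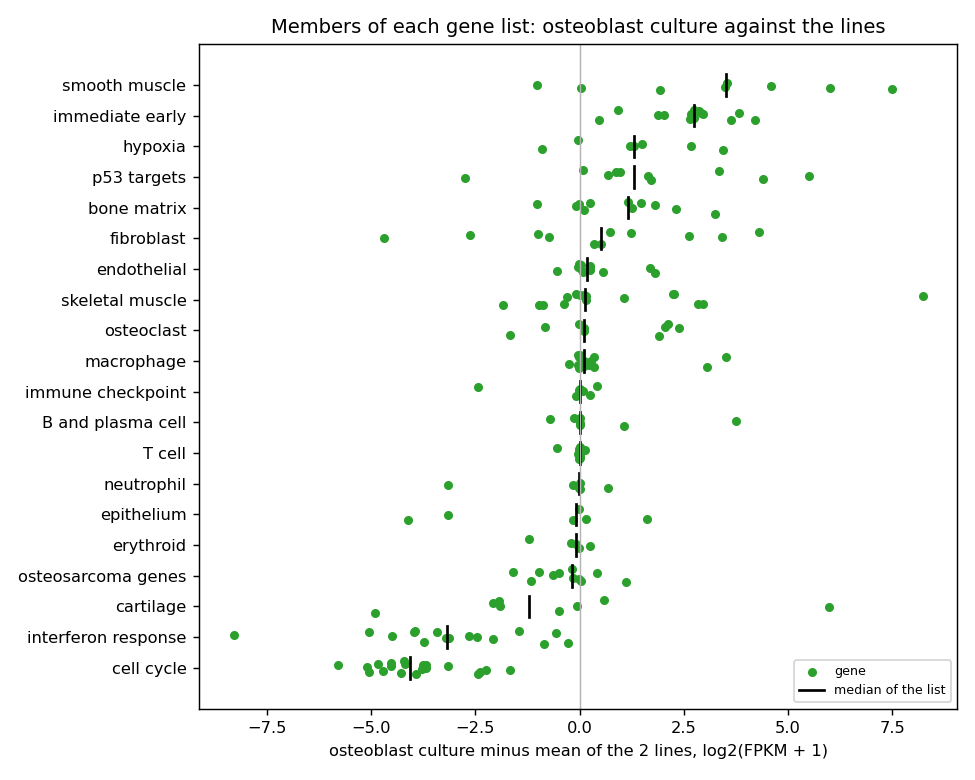
Difference in log2(FPKM + 1) between the osteoblast culture and the mean of the 2 lines for each member of 20 gene lists, 1 point per gene, with the median of each list as a black bar. Cell cycle genes lie below 0 in 20 of 20 cases (median -4.06) and smooth muscle genes have the highest median (3.50).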

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

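The tests with DOS.100 and DOS.32 as 1 tumour and with gene symbols only were chosen after the results were seen, and they moved none of the counts below by over 1.5 times. The 2489 genes called between lines and tumours stayed between 2315 and 2760 under the pseudocount of 0.1, no filter, both scalings, DOS.46 and DOS.46.2 as 2 tumours and plain eBayes. Leaving out a line gave 344 to 1998 (199 to 979 higher, 145 to 1019 lower), with 320 of the 344 and 1504 of the 1998 among the 2489, and the remaining line is then assumed to vary like the tumours. Adding the osteoblast culture to the lines gave 4580 (2548 higher and 2032 lower), and the cause was not tested. Title numbers occur in both groups for 2 pairs, and whether a pair comes from 1 dog is not given in the sources used here. The difference between the lines correlated at r = 0.269 across genes with that between the tumours of their numbers. With the number as a fixed replicate block on 4 libraries limma called 0 genes (0 higher and 0 lower, 3205 at an unadjusted p below the threshold), where few samples remain. As a replicate block by estimated correlation (0.833) it called 7612 (3897 higher and 3715 lower). In that fit DOS.46 and DOS.46.2 also formed a block, so 0.833 is not a correlation of lines with tumours alone. Libraries with a shared number correlated most with each other in 3 of 4 cases, with OSCA.78 the exception (r = 0.239 with DOS.78, 0.301 with DOS.116), and in 2 of 4 over the 2000 genes of largest SD, where OSCA.8 also came nearest to DOS.116 (0.304, and 0.268 with DOS.8).

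The number of lists called by camera, 6, was 0 with an estimated correlation and between 4 and 9 under the other settings. List scores passing the exact permutation test were 9 instead of 5 with a pseudocount of 0.1. When a line was left out 30 splits remain, too few for a single list to pass after adjustment, so that setting cannot decide. Mean list changes reversed with the osteoblast culture added for cell cycle (-0.53), hypoxia (0.11) and p53 targets (0.37), and for the genes TNFRSF13C (0.24) and LEP (1.15). The p53 list ran from -0.383 to 0.0216 with a line left out, the second without OSCA.78, and was 0.00919 under the fixed replicate block. The erythroid list reversed after quantile normalisation (0.0794), under the fixed block (0.14) and under the block by estimated correlation (0.10). None of these lists but the cell cycle was called. Score correlations past the threshold were 5 instead of 3 without a filter. After removal of the first principal component the correlation of T cell with endothelial scores (-0.0685), of cell cycle with macrophage scores (0.20) and of bone matrix with macrophage scores (0.0627) reversed, as did cell cycle with bone matrix after quantile normalisation (0.0455). With a pseudocount of 0.1 the odds ratio of fibroblast genes among the most variable was 0.900. The osteoblast culture's higher genes were 1387 after quantile normalisation and 3234 to 3651 against 1 line, its lower genes 2268 with a pseudocount of 0.1 and 2308 to 2595 against 1 line, and a single reference line removes a requirement. Other causes were not tested. Of 884 values for named genes between lines and tumours under alternatives, 745 kept direction and side of the threshold, 106 lost the call and 31 gained one. Read depth is unknown, so low values such as those of the T cell genes limit the fold changes by an unknown amount.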

Other observations

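The tests of random tumour pairs and of scaling for the lower genes of the lines, and that of a shared level in DOS.100 and DOS.32, were chosen after the result was seen, and the genes and tumours named here were chosen after their values were seen.

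A few tumours had high scores for genes of other tissues. The mast cell and adipocyte lists held only 4 genes each, and adipocyte genes were low, with LEP at most 1.24 and PLIN1 at most 4.59 FPKM in any primary tumour. DOS.110 had the highest scores for skeletal muscle (3.51, against a mean of 1.41 with an SD of 0.66 over 29 tumours), mast cells (4.14 against 1.15 with an SD of 0.89) and adipocytes (2.16 against 0.61 with an SD of 0.39). The mast cell protease CPA3 stood at 64.1 FPKM there against a median of 0.196, and the muscle actin ACTA1 at 81.9 against 1.24. DOS.28 came next for skeletal muscle (3.34), with the troponin TNNI2 at 54.2 FPKM against a median of 3.70, and its mast cell and adipocyte scores were 0.41 and 0.62. DOS.85 held the highest neutrophil score (4.19), with the alarmin S100A12 at 568 FPKM against a median of 8.57, followed by DOS.114 (3.72).

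Single genes stood out in single tumours. Cyclin E gene CCNE1, an osteosarcoma list member, reached 34.4 FPKM in DOS.24 against a median of 5.39. Of the 10 genes with the largest rise in the lines, PLA2G3, CDH6, MGST1 and TLX2 had their highest primary tumour value in DOS.8, at 3.16, 2.46, 19.9 and 5.09 FPKM. The tumour DOS.76 had 1329 genes above the range of the other 28, the most of any tumour. In DOS.76 the bone genes DMP1 (762 FPKM) and SFRP4 (699) and the neuropeptide NPY (505) also reached their highest values.

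In the lines, 1201 genes were lower than in the tumours. Among 100 random pairs of primary tumours set against the remaining tumours the highest count of lower genes was 41, and the closely alike pair DOS.100 and DOS.32 gave 255, which argues against any 2 tumours giving as many. Of the 1201, 78.1% stayed called lower after quantile normalisation, which argues against scaling between libraries as the whole cause. With list members left out, 28.3% of 1159 lower genes followed the macrophage or the endothelial score across tumours (r over 0.5), against 3.70% of higher genes and 9.88% (highest of 200 draws 12.3%) of uncalled genes matched on mean and SD. A candidate explanation for that part is that the lines lack macrophages and vessel cells present in tumour samples, as CD74 and PLVAP went from 277 and 260 FPKM in tumours to below 1 FPKM in both lines. The bone matrix and matrix-protein falls need not follow it, and the other lower genes stay open. The osteoblast culture also lay below every primary tumour by bone matrix score (4.68, lowest tumour 5.06). Other genes lower in the lines, such as FXYD1 (768 FPKM) and NDUFA4L2 (4064), stood above every tumour in it. It is 1 library, so an effect of culture could not be tested apart from the lines.

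Tumours DOS.100 and DOS.32 resembled each other like repeats of 1 sample. Their deviations from the tumour mean correlated at r = 0.843. Of 3265 abundant genes with a symbol, 4 differed by over 2-fold, against at least 135 in the 433 other pairs of different numbers. Rows named by an Ensembl identifier only were left out of that count. Those rows took 36.7% of the summed FPKM in DOS.100 and 56.8% in DOS.32. The 10 most abundant genes took 14.3% and 39.1%, so the libraries were not alike in every respect. Of 134 genes with a symbol that are on in some tumours and off in others, those clearly on or off in both libraries were compared. They were in the same state in 100% of cases (67 of 67), as for DOS.46 and DOS.46.2 (59 of 59), while the highest other pair reached 90.6%. The lower 95% binomial bound of the 100%, 94.6%, lies above the highest other pair. It takes the 67 genes as independent, which they are not, so no conclusion is drawn from the bound. The 67 comprise 42 genes on and 25 off in both, which argues against a shared level set by normalisation or depth. The 2 libraries may come from 1 tumour or 1 dog under different numbers. Treating them as 1 tumour gave 2504 called genes in place of 2489.

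MDM2, a ubiquitin ligase, stood at 487 FPKM in DOS.28 against a median of 44.7 in the other tumours and 65.5 in the next. The other 9 p53 targets ranked DOS.28 at 12 of 29, just past the bound fixed beforehand against a general p53 response. A rank so near that bound argues against such a response only weakly. A gain of the chromosome region was tested on the 11 measured genes within 1 Mb of MDM2 in the reference table, of which 18.2% (2 of 11) were highest in DOS.28, where chance gives 3.45%, and that share of 18.2% lies between the bounds fixed beforehand for and against a gain. Those genes, CPM (66.5 FPKM against a median of 7.27) and YEATS4 (25.04 against 7.58), lie on the same side of MDM2 with CPSF6 (33.1 against 23.2) and LYZ (23.8 against 49.7) between them, while FRS2 (4.19 against 10.7) and CCT2 (25.7 against 43.5) beyond them and all 5 genes on the other side stood below their medians. A gain of part of that region could give the higher genes and not the lower ones, but 523 of 10530 windows of as many genes along the genome held as large a share, so a gain and a change confined to single genes cannot be told apart.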
